A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

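The samples were 6 libraries of polyadenylated RNA from Saccharomyces cerevisiae grown to mid-log phase, 3 from a strain with JHD2 deleted and 3 from wild type. Per the labels, RNA was extracted with hot acid phenol and the libraries were made by 3′READS, in which RNA fragments carrying a poly(A) tail are captured and sequenced at their 3′ ends, so that each read marks where a transcript was cleaved and polyadenylated (its pA site). Nothing in the labels says whether replicates came from separate cultures. The p-values for single genes and for library averages therefore measure the spread between these libraries, which may be technical.

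The deposited table holds read counts per cluster of pA sites and library, not normalized. Per the series description, the authors trimmed adapters, aligned single-end reads longer than 15 bp to sacCer3 with Bowtie2 in local mode after removing 4 bp from the 5′ end, and kept alignments with a mapping quality of 10 or more, mismatches of at most 5% and 2 or more unaligned T bases at the 5′ end. The version of Bowtie2 is not given in the sources used here. Per the same description, the ends of these reads were clustered within 24 bp, each cluster was given to a gene of the yeast genome database extended by up to 1000 bp past its coding end, and clusters with fewer than 3 reads or under 5% of the reads of the gene were removed. The gene extension means that a cluster can lie in a neighbouring transcript. The unaligned T bases keep reads that begin in a genomic run of A from being counted as tails, and the read direction gives the strand.

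The table was tested against these statements. It holds 13565 clusters in 4014 genes, each gene with at least 2 clusters and at most 10, so the column totals are not library depths and genes with a single cluster were not analysed here. The smallest summed count was 3. Of the clusters, 2748 held under 5% of the reads their gene has in the table and 572 were under 5% in every library, and the sums to which the deposited rule was applied are not given in the sources used here. Gene identifiers were looked up in the RefSeq annotation of the same assembly (R64), where 4013 of 4014 were found. No cluster lay more than 1000 nt past its gene, and 79.6% of clusters with 97.8% of reads lay past the stop codon. Whether the deposited positions count from 0 or 1 is not given in the sources used here, so they are printed as deposited and distances can be off by 1 nt. All 6 columns matched a library label.

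For mRNA level, reads were summed over the clusters of a gene and compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, default low-count filter, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as TMM-scaled counts per 1e6 reads (CPM). Those of genes are scaled to the reads of the tested genes, and those of single clusters to the reads at retained clusters. Cluster levels therefore do not add up to the level of their gene. Standard errors were obtained from the fold change and its F statistic. For pA site usage, clusters with a summed count of 20 or more were retained, and the genes with 2 or more of them were tested with the gene-level F test of the edgeR function diffSpliceDGE, which asks whether the clusters of a gene changed by different folds. The direction came from the read-weighted mean position of the 3′ end, in nt past the most upstream retained cluster. As library-wide readouts, this mean position and the share of reads at the most distal cluster were averaged over genes with a mean of 20 or more reads per library, and the 3 values per group were compared with an exact two-sided permutation test. That test cannot give a p below 0.10 here.

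A set of 28 gene lists fixed before the data were examined was tested with camera of limma 3.58.1 (inter-gene correlation 0.01) where 5 or more members were tested, and again with an estimated correlation. With the preset correlation, camera sets the members against the other genes, so its p reflects mainly the spread between genes and not that between libraries. The test fry was run as well, which compares each list with no change and not with the other genes. Genes are named by a rule fixed at the same time: JHD2, the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of 20 or more reads per library in the higher group and no overlap between groups, and the 2 members of each list with the smallest p. For site usage the rule takes genes past the threshold whose mean positions do not overlap between groups. Genes named outside the rule are marked as such or belong to a list described as a group. The 200 nt before the most-read cluster of each gene were aligned to the genome, and 26 of 4013 genes had a stretch of 100 nt or more at 95% identity or more elsewhere. Their reads are uncertain, since a mapping quality filter can remove them unevenly.

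The tests were run on simulated counts with known changes in 200 genes. For mRNA level (3292 genes), 43.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 92.4% of those changed 3-fold were recovered, with 4.70% false calls. For site usage (2380 genes), a change of 1 cluster by 2-fold was recovered in 29.9% of genes, by 3-fold in 53.7% and by 4-fold in 78.8%, with 5.26% false calls. Alternatives covered DESeq2 1.42.0 (size factors and its Wald test), limma-voom, the Simes test, count filters, the number of clusters used, thinning of reads, a replicate term and leaving out each library. Chosen after the data were seen were the use of clusters past the stop codon only and the removal of genes matching elsewhere in the genome. Intervals and upper limits for single counts cover counting error only.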

Results

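3′ ends of polyadenylated RNA were counted in 3 libraries of budding yeast lacking JHD2 and in 3 wild-type libraries. JHD2 encodes a histone demethylase of the KDM5 family, and the series asks whether such enzymes maintain the length of 3′ untranslated regions (UTRs). The table held 424996, 380332 and 480847 reads in deletion replicates 1, 2 and 3 and 368419, 233749 and 277202 reads in wild-type replicates 1, 2 and 3. JHD2 itself had 0 clusters in the table, which lists only genes with 2 or more, so the deletion could not be checked from its own reads. No replicate pair differed by less than sampling noise, the chi-square per degree of freedom being 1.41 or more in every pair. Wild-type replicate 2 stood apart: its log-scaled levels correlated with those of the other wild-type libraries at 0.946 on average across genes. The value was 0.957 and 0.955 for wild-type replicates 1 and 3 and at least 0.973 for the deletion libraries. Wild-type replicates 1 and 3 correlated with each other at 0.966 and with the deletion libraries at 0.963 and 0.961 on average. Their averages with the deletion libraries thus exceeded those within their own group. Coordinates refer to sacCer3. Levels are scaled counts per 1e6 reads (CPM), with different totals for genes and for single clusters. Values with an error are mean ± SD with n = 3 libraries per group unless an SE is named.

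The relative use of pA sites changed in 5 of 2380 tested genes, and in all 5 the mean 3′ end lay farther downstream in the deletion than in wild type. These were URA3, which encodes an enzyme of pyrimidine synthesis (by 41.2 nt), YGP1, a secreted glycoprotein of nutrient-limited cells (by 195 nt), SOD2, the mitochondrial manganese superoxide dismutase (by 110 nt), PCL1, a cyclin (by 60.5 nt), and SBE22, a gene of bud growth (by 8.47 nt). In URA3, YGP1 and SOD2 the mean positions of the groups did not overlap. PCL1 and SBE22 fell outside the naming rule and are named because the count is small. A share of 5 of 5 in one direction has an exact binomial p of 0.062. That test takes genes as independent, although all were measured in the same libraries. By edgeR with Benjamini-Hochberg adjustment, 0 genes were called with an earlier mean end. At an unadjusted p under 0.05 there were 53 genes with a later and 82 with an earlier mean end, 135 in all against 119 expected by chance. The alternative test of limma-voom called 2 genes (URA3 and YGP1) and the Simes test 1 (YGP1), all of them with a later mean end.

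URA3 (YEL021W, chromosome V, 116167 to 116970, plus strand) had its most upstream cluster at position 117044, 74 nt past the stop codon in the 3′ UTR. This cluster held 10, 3 and 13 reads in the wild-type libraries and 0 in each deletion library. The cluster at 117106, 136 nt past the stop codon, held 5, 6 and 12 reads in the deletion and 9, 2 and 2 in wild type. Of the URA3 reads at these clusters, 100% lay at the distal one in the deletion and 33.6% ± 17.9 in wild type (adjusted p = 0.0029, edgeR). A cluster at 117073, below the count minimum, had 0 reads in the deletion and 3 in wild type. With 23 URA3 reads in the deletion, a count of 0 allows a share of up to 13.0% at the upstream clusters. The level of URA3 mRNA was too low to pass the filter of the mRNA test.

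The YGP1 change (YNL160W, chromosome XIV, 336545 to 337609, plus strand; adjusted p = 0.0040, edgeR) compared a cluster inside the coding region with one in the 3′ UTR. The cluster at 336564, 19 nt into the gene, stood at 105 ± 10.5 CPM in the deletion and 79.1 ± 15.5 in wild type. The cluster at 337839, 230 nt past the stop codon, stood at 878 ± 77.2 and 226 ± 26.3. The YGP1 share at the cluster in the coding region was 10.7% ± 1.75 in the deletion and 26.0% ± 5.95 in wild type. This smaller share went with the higher level of the cluster in the 3′ UTR. The mRNA of YGP1 was itself called higher in the deletion (log2 fold change 1.68, SE 0.15). In SOD2 (YHR008C, chromosome VIII, 122889 to 123590, minus strand; adjusted p = 0.046, edgeR) the clusters 158 and 227 nt past the stop codon lie in the same-strand gene YHR007C-A. They stood at 75.8 ± 20.4 and 99.3 ± 18.3 CPM in the deletion and at 209 ± 38.0 and 292 ± 42.9 in wild type. The SOD2 cluster at 121894, 995 nt past the stop codon and 211 nt before the start of ERG11, stood at 47.5 ± 18.5 CPM in the deletion and 39.4 ± 11 in wild type, so its larger share (21.4% ± 8.13 against 7.50% ± 2.82) went with the lower level of the other clusters. With the 2 most-read clusters of each gene, which leave this one out, the SOD2 mean end moved by -0.946 nt (adjusted p = 0.98, edgeR).

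In PCL1 (YNL289W, chromosome XIV, 87897 to 88736; adjusted p = 0.041, edgeR) the cluster 120 nt past the stop codon held 29.2% ± 7.99 of reads in the deletion and 49.7% ± 19.7 in wild type, and the cluster 404 nt past it 37.6% ± 8.49 and 20.5% ± 10.2. The PCL1 cluster at 89213, 477 nt past the stop codon, lies in the small nucleolar RNA gene SNR40 (89210 to 89306). In SBE22 (YHR103W, chromosome VIII, 320414 to 322972; adjusted p = 0.046, edgeR) the cluster 273 nt past the stop codon took 46.8% ± 1.12 of reads in the deletion against 22.6% ± 3.93 in wild type. Both the SBE22 cluster at 44 nt (11.6% ± 2.27 against 25.3% ± 6.14) and the one at 434 nt (13.9% ± 4.22 against 26.7% ± 3.51) held less, the latter lying 3 nt before the start of GRE3.

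The calls for site usage depended on single libraries: 0 genes were called without wild-type replicate 3, 1 without wild-type replicate 1 (URA3) and 4 without wild-type replicate 2, which lost SBE22. Without deletion replicate 1 or 2, 2 genes were called (URA3 and YGP1), and without deletion replicate 3, 2 others (SOD2 and PCL1). With clusters past the stop codon only, an alternative chosen after the data were seen, URA3 remained called, YGP1 had 1 cluster and was not tested, and the adjusted p of PCL1, SBE22 and SOD2 was 0.061.

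**Figure D1:**
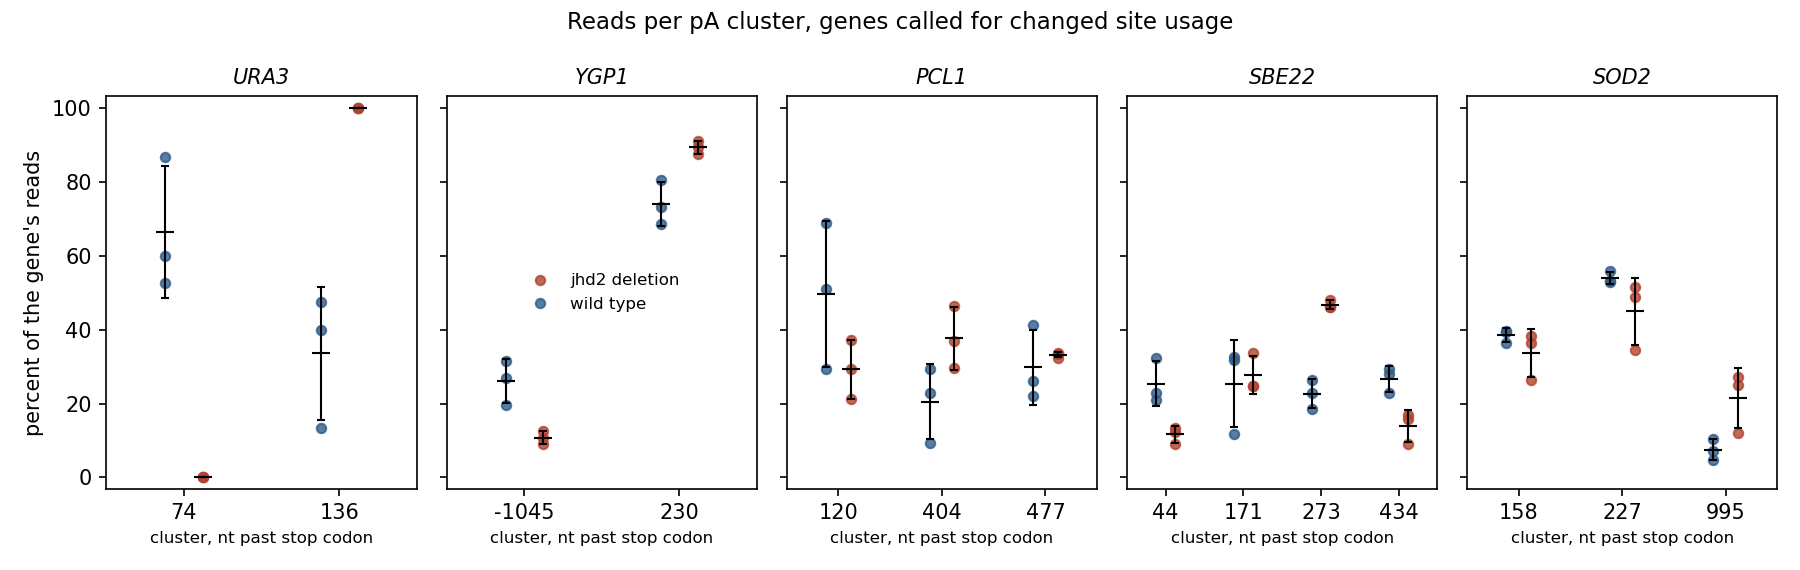
Percent of the gene's reads at each retained pA cluster (x axis: nt past the stop codon, negative inside the coding region) for the genes called for changed site usage, with dots for libraries and bars for mean ± SD (n = 3). All 3 deletion libraries sit at 100% at the URA3 cluster 136 nt past the stop codon, above each wild-type library.

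Across genes, 3′ ends lay at the same average position in both strains within the spread of the libraries. The mean pA position over 1919 genes was 208 nt ± 1.29 past the most upstream cluster in the deletion and 208 nt ± 0.970 in wild type, a difference of 0.053 nt (exact permutation test, two-sided p = 1, n = 3 per group). The share of reads at the most distal cluster was 39.1% ± 0.157 in the deletion and 39.7% ± 0.479 in wild type, lower by 0.60 percentage points (difference -0.598, exact permutation p = 0.20, where 0.10 is the smallest possible). Of the tested genes, 1051 had a later and 1329 an earlier mean end in the deletion. Setting deletion replicates 1 and 3 with wild-type replicate 3 against the other libraries gave the same counts, 1051 and 1329. Without wild-type replicate 2 the difference in distal share was -0.330 points, and the difference in mean position fell below 0 without deletion replicate 1 (-0.776 nt) or 2 (-0.054) and without wild-type replicate 1 (-0.142) or 2 (-0.554).

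**Figure D2:**
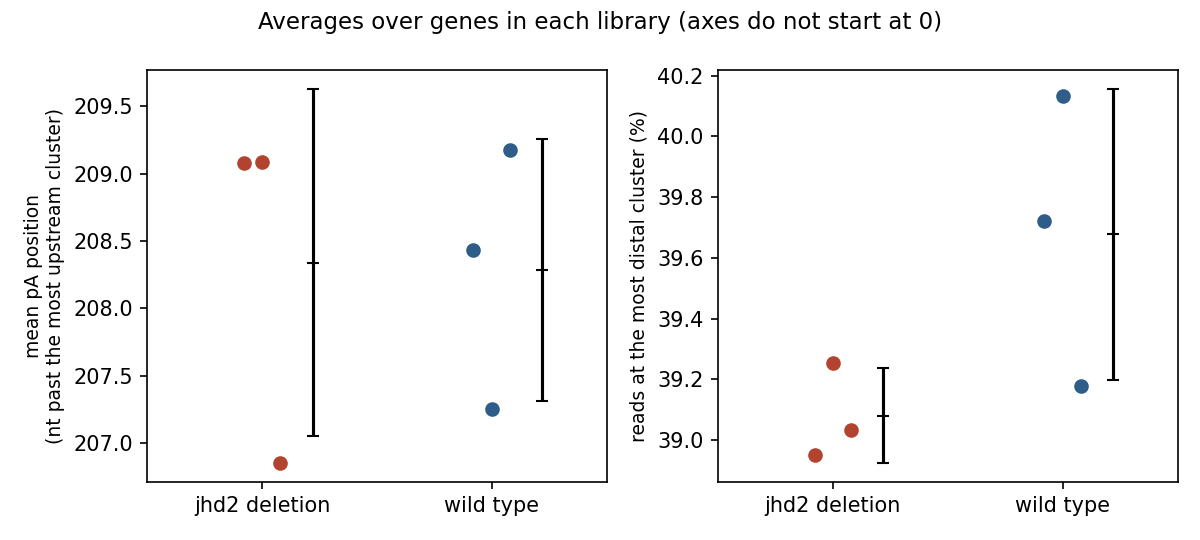
Mean pA position over genes (left, nt past the most upstream retained cluster) and percent of reads at the most distal cluster (right) in each library, as dots, with mean ± SD (n = 3) beside them; the axes do not start at 0. The mean positions of the groups overlap, from 206.9 to 209.1 nt in the deletion and from 207.3 to 209.2 nt in wild type.

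The mRNA level changed in 44 of 3366 tested genes, with 36 higher and 8 lower in the deletion, and the higher ones included GPH1, HXK1, TPO2 and HXT4. GPH1, the glycogen phosphorylase, rose from 93.5 ± 46.7 to 534 ± 56.1 CPM (log2 fold change 2.43, SE 0.21), and GSY2, a glycogen synthase, from 49.6 ± 16.8 to 203 ± 10.3 (1.98, SE 0.23), while GSY1, the other glycogen synthase gene, did not pass (0.69, SE 0.22, adjusted p = 0.15, edgeR). The hexokinase HXK1 rose from 286 ± 84.9 to 1188 ± 134 (2.04, SE 0.17) and the hexose transporter HXT4 from 42.5 ± 8.57 to 190 ± 51.5 (2.19, SE 0.26). Higher too were the polyamine transporter TPO2 (2.23, SE 0.18), the membrane proteins YRO2 (2.17, SE 0.20) and HSP30 (1.98, SE 0.17), and the stress-induced DDR2 (1.91, SE 0.42) and TMA10 (1.77, SE 0.36). The adjusted p of these 9 genes in edgeR ran from 5.2e-12 to 0.0066.

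The hexose transporter HXT6 had 65 reads in the deletion and 3 in wild type, a ratio of 15.0 after scaling, with an exact 95% interval of 4.90 to 74.4 for counting error. Reads of HXT6, HXT7 (log2 fold change 1.56, SE 0.16) and the acid phosphatase PHO11 (1.53, SE 0.32) are uncertain because near-identical stretches lie elsewhere in the genome. GPH1 (YPR160W) lies on chromosome XVI from 861306 to 864014, HXK1 (YFR053C) on VI from 253592 to 255049, GSY2 (YLR258W) on XII from 660716 to 662833, HXT4 (YHR092C) on VIII from 287081 to 288811 and HXT6 (YDR343C) on IV from 1159608 to 1161320. Levels were sums over all clusters of a gene, mostly in its 3′ UTR.

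Lower in the deletion were DAN1, a cell wall mannoprotein of anaerobic cells (15.9 ± 9.96 against 73.5 ± 55.2 CPM; log2 fold change -2.33, SE 0.43), SOD2 (202 ± 17.8 against 491 ± 67.1; -1.29, SE 0.16) and the cyclin CLN1 (79.5 ± 15.9 against 159 ± 32.8; -1.01, SE 0.22). Smaller decreases were called for THI6, of thiamine synthesis (-0.95, SE 0.20), GCN1, of the amino acid starvation response (-0.74, SE 0.19), the cell wall protein TIP1 (-0.67, SE 0.13) and ILV5, of branched-chain amino acid synthesis (-0.51, SE 0.13). The kinase gene KCC4 (-1.25, SE 0.34) was the remaining lower call and is named outside the rule. DAN1 (YJR150C) lies on chromosome X from 708811 to 709707 and CLN1 (YMR199W) on XIII from 662644 to 664284.

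Groups did not overlap in 15.6% of all tested genes, where 10% is expected by chance, nor in any of the 44 called genes, which were selected for a difference between the same libraries. The median log2 fold change of all tested genes was -0.00026, and 25 of the higher and 4 of the lower genes differed at least 2-fold. Without wild-type replicate 1 there were 15 lower genes and DAN1 lost its call (log2 fold change -1.45, adjusted p = 0.15, edgeR), its wild-type mean resting on that library (136 CPM against 30.4 and 54.3 in the others). Without deletion replicate 2 there were 4 lower genes and CLN1 lost its call (0.079). GCN1 and THI6 lost theirs without wild-type replicate 2 (-0.24, adjusted p = 0.54, and -0.53, adjusted p = 0.065), their wild-type means resting on that library. Calls were also lost for DDR2 without deletion replicate 1 (0.086) and TIP1 without deletion replicate 3 (0.052). GCN1 also lost its call without deletion replicate 1 (0.0502), 2 (0.23) or 3 (0.12), and ILV5 without any library except wild-type replicate 2 (0.063 to 0.17). KCC4 lost its call without any 1 library other than wild-type replicate 1. The DESeq2 Wald test called 26 genes in all, and of the genes named here it did not call HXT6, DDR2, TMA10, PHO11, CTT1, SDH3, CTS1, DAN1, GCN1 or KCC4. That test left 979 genes without an adjusted p, and a gene without one counts here as not called.

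**Figure D3:**
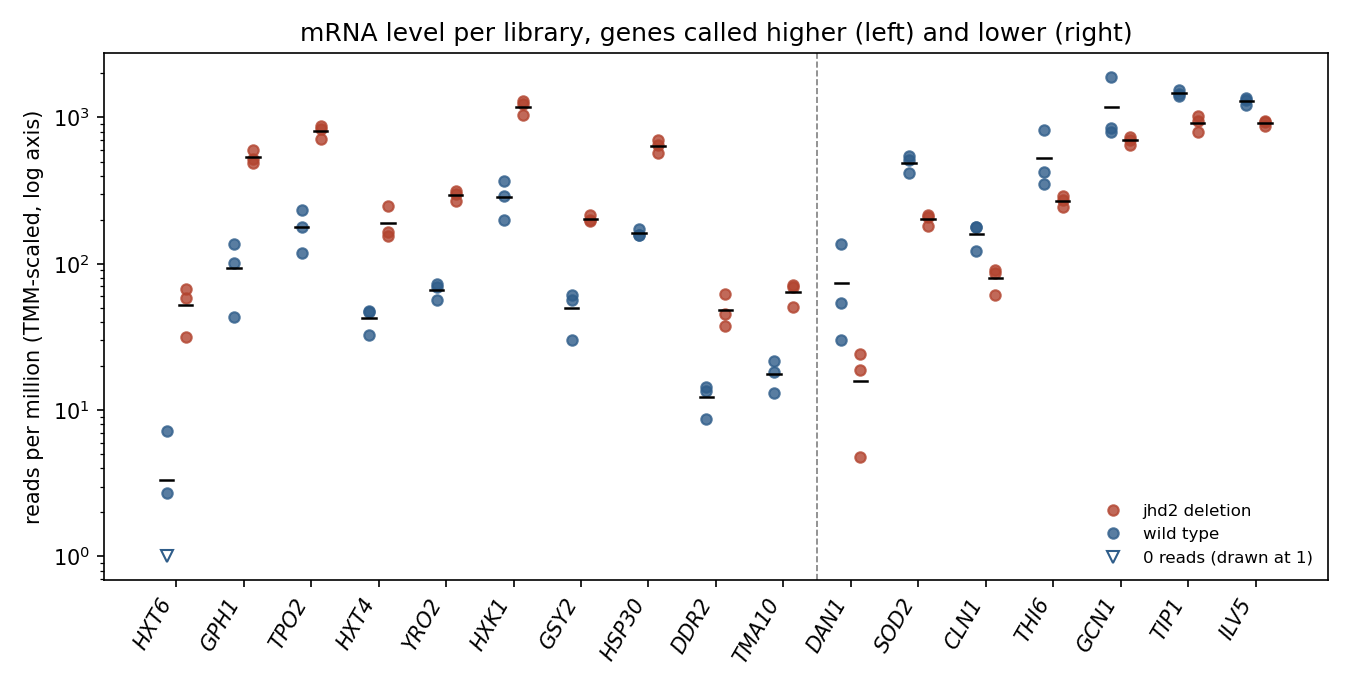
CPM (log axis) in each library for the genes with the largest changes, higher in the deletion on the left of the dashed line and lower on the right, with bars for the mean of 3 libraries and an open triangle for a library with 0 reads. The deletion and wild-type libraries do not overlap in any of them, GPH1 standing at 534 ± 56.1 against 93.5 ± 46.7.

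Among the fixed gene lists, genes of the general stress response rose as a group. Of 23 tested members, 8 rose (HXK1, GPH1, YGP1, SPI1, GSY2, PGM2, DDR2 and CTT1), 0 fell and 15 did not pass over all genes. When adjusted over the list alone 13 rose. Of the tests that leave out 1 library, CTT1, the cytosolic catalase, kept its call in those without deletion replicate 1 and without wild-type replicate 3. The median log2 fold change of the list was 0.51 (camera adjusted p = 3.7e-23, and adjusted p = 0.018 with an estimated correlation). The wall protein SPI1 rose by 1.73 (SE 0.18) and the phosphoglucomutase PGM2 by 1.61 (SE 0.19), while the small heat shock gene HSP12, another member, had 0.51 (SE 0.27, adjusted p = 0.55, edgeR). The heat shock genes SSA3 and SSA4 had -0.20 (SE 0.22) and -0.33 (SE 0.37).

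The hexose transport and galactose list had a median of 0.38 over 9 members (camera adjusted p = 9.0e-07, and adjusted p = 0.042 with an estimated correlation). Of these, 3 rose, HXT4 and the HXT6 and HXT7 genes with uncertain reads, 0 fell and 6 did not pass, among them the transporter gene HXT2 (-0.14). In all 4 rose when adjusted over the list alone, the added one being the invertase gene SUC2 (0.59, SE 0.22). GAL2, GAL4 and GAL80 of galactose use had 0.38, 0.01 and -0.01. The TCA cycle and respiratory chain list rose with a median of 0.31 (camera adjusted p = 1.3e-11, and adjusted p = 0.042 with an estimated correlation), and 34 of its 35 members lay above 0. Of these, 1 rose over all genes, SDH3 of succinate dehydrogenase (0.68, SE 0.18), and 11 when adjusted over the list alone, among them QCR10 (0.76, SE 0.21; called over all genes without deletion replicate 3, adjusted p = 0.046, or wild-type replicate 3, 0.0025) and CIT1, the citrate synthase (0.47, SE 0.14). SDH3 lost its call without any 1 of the deletion replicates and without wild-type replicate 2 or 3 (adjusted p from 0.063 to 0.29, edgeR).

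The phosphate starvation list had a median of 0.38 over 13 members (camera adjusted p = 6.7e-05), with adjusted p = 0.056 with an estimated correlation. PHO11 rose, and 6 members rose when adjusted over the list alone, VTC4 of polyphosphate synthesis among them (0.38, SE 0.13). Glycolysis and fermentation had a median of 0.18 over 8 members (camera adjusted p = 0.0053, and adjusted p = 0.14 with an estimated correlation). There 1 member passed, HXK1, and FBA1 had 0.25 (SE 0.12). HXK1 (2.04) belongs to the stress list as well, and the other tested members ran from -0.17 (PFK1) to 0.38 (PDC5). Below 0 lay the iron regulon, with a median of -0.34 over 11 members (camera adjusted p = 0.0053, and adjusted p = 0.19 with an estimated correlation), and the protein folding list, with -0.15 over 11 members (0.015, and adjusted p = 0.19 with an estimated correlation). 0 members of either passed over all genes by edgeR. The lowest p were those of FIT2 (-0.49, SE 0.18) and FIT1 (-0.66, SE 0.27), cell wall mannoproteins of iron uptake, and of the chaperones HSP82 (-0.51, SE 0.14) and HSP60 (-0.48, SE 0.16), and adjusted over the list alone 0 iron genes and 2 chaperone genes passed. The iron list lost its call without wild-type replicate 1 (adjusted p = 0.21) or deletion replicate 3 (0.063), and the folding list without wild-type replicate 3 (0.15) or deletion replicate 2 (0.053). FIT1 and FIT2 were called without wild-type replicate 2 (0.031 and 0.032), while without wild-type replicate 1 FIT1 stood at 0.17 (adjusted p = 0.88) and FIT2 at -0.15 (0.83), so that their values rest on that library. HSP82 was called without wild-type replicate 1 (0.0028) and with DESeq2 size factors (0.045), and HSP60 without deletion replicate 1 (0.047) or wild-type replicate 1 (0.034).

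**Figure D4:**
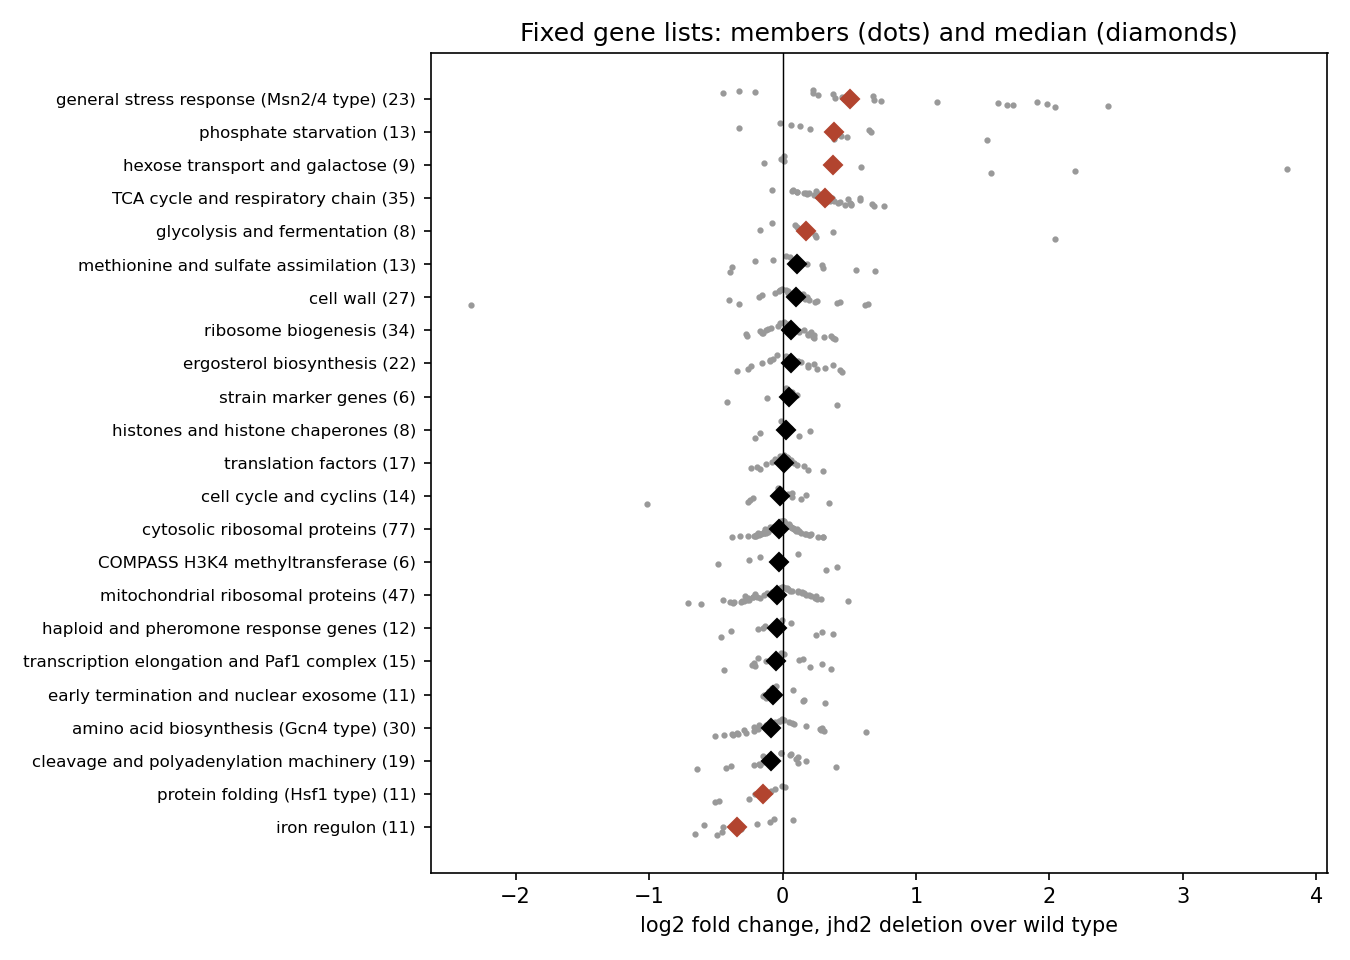
Log2 fold change (deletion over wild type) of each tested member (dots) and the median (diamonds, red where camera passed the threshold) for the 23 lists with 5 or more tested members, whose number is in brackets. The general stress response has the highest median, 0.51, and the iron regulon the lowest, -0.34.

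Lists of genes that act on the histone mark or on 3′ ends did not pass, and 0 of their members were called for mRNA level or for pA site usage. The median was -0.02 over 6 members of the COMPASS histone methyltransferase, -0.09 over 19 members of the cleavage and polyadenylation machinery, -0.07 over 11 genes of early termination and the nuclear exosome and -0.05 over 15 elongation genes (camera adjusted p from 0.58 to 0.999). Their members with the smallest p were SET1 (0.32) and BRE2 (0.41), CFT1 (-0.64) and NAB2 (-0.43), NAB3 (0.32) and LRP1 (0.15), and SPT4 (-0.44) and POB3 (0.37). Of the demethylase relatives 2 were tested, ECM5 (-0.47, SE 0.34) and GIS1 (0.13, SE 0.18). NAB2 was called without wild-type replicate 1 (adjusted p = 0.048, edgeR).

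The ribosomal protein genes, 77 tested, had a median of -0.02 (camera adjusted p = 0.48), with RPL34B at -0.38 (SE 0.13; called without wild-type replicate 1, adjusted p = 0.019, edgeR) and RPS15 at 0.30 (SE 0.13). Amino acid biosynthesis had a median of -0.09 over 30 members (0.054), ILV5 being its only call and SER3 at -0.44. This list passed camera with DESeq2 size factors and without wild-type replicate 2. The remaining lists did not pass, with camera adjusted p from 0.19 to 0.999. Medians of growth-related lists were 0.06 for ribosome biogenesis (NSA1 0.39, DBP9 0.38), 0.01 for translation factors (HYP2 0.30, EFT2 0.19) and -0.04 for mitochondrial ribosomal proteins (RSM10 -0.61, MRPS16 -0.37). They were 0.03 for histones and their chaperones (HTA2 -0.21, HHO1 0.12), 0.11 for sulfate assimilation (MET14 -0.39, SAM2 0.69) and 0.06 for ergosterol synthesis (ERG6 0.44, ERG27 -0.34). Pheromone response had -0.04 (STE4 -0.46, SST2 0.25), strain markers 0.05 (CAN1 0.41, ADE2 -0.41) and the cell cycle list -0.02 (CLN1 called, SIC1 0.35). The cell wall list had 0.10, with DAN1 called lower and the chitinase gene CTS1 called higher (0.61). CTS1 lost its call without deletion replicate 1 or 2 or wild-type replicate 1 or 3 (adjusted p from 0.058 to 0.33, edgeR).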

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

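The alternatives without clusters in the coding region and without genes matching elsewhere in the genome were chosen after the data were seen. A count was taken as kept within 1.5 times the main value and as moved beyond that. A library-wide difference was taken as kept when its direction and side of the threshold stayed, whatever its size. Its exact test cannot give a p below 0.10, so the side of the threshold could not change and only the direction was at stake. Of the comparisons of counts and library-wide differences with an alternative, 67 were kept, 35 moved and 8 changed sign. Of those for named genes and lists, 534 kept direction and side of the threshold, 62 lost their call, 10 gained one and 4 changed sign. Genes with changed mRNA level (44, 36 higher and 8 lower) numbered 26 (21 and 5) by the DESeq2 Wald test, which left 979 genes without an adjusted p, 27 (3 lower) with the most-read cluster of each gene, 45 with DESeq2 size factors, 41 by limma-voom, and 5 lower with a mean of 20 or more reads, where fewer genes were tested. Without each library the number ran from 30 to 51 and that of lower genes from 4 (deletion replicate 2) to 15 (wild-type replicate 1). Of the 44 genes, 30 to 36 stayed called without any 1 library, and none of them changed sign in any alternative.

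Genes with changed pA site usage, 5 in the main test, numbered 3 with a summed count of 1 or more, 1 with 100 or more, 1 by the Simes test, 2 by limma-voom, 2 with the 2 most-read clusters and 1 with clusters past the stop codon only, all with a later mean end, and from 0 to 4 without each library. With a count of 100 or more and with the 2 most-read clusters, SOD2, no longer called, changed direction (-0.946 nt in both). The lists past the threshold fell from 7 to 3 with an estimated correlation and were 8 with DESeq2 size factors. The test fry asks another question, each list against no change, and passed 6 lists, 5 of them among the 7: protein folding and the iron regulon did not pass, and amino acid biosynthesis did. The difference in mean pA position changed sign with a summed count of 1 or more (-1.79 nt), as a median over genes (-0.818), with thinned reads (-0.454) and with clusters past the stop codon only (-0.572), and ran from -0.776 to 0.580 nt without each library. That in distal share stayed below 0 in every alternative, from -1.14 to -0.330 points. Uncalled genes that changed sign without a library were HHO1 (from -0.023 to 0.27), FIT1 (from -0.93 to 0.17), MF(ALPHA)2 (from -0.061 to 0.30) and SPR3 (from -0.081 to 0.71). The cause of these changes between alternatives was not tested.

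With replicate numbers as a block, 33 genes changed in mRNA level (28 higher, 5 lower), 2 in site usage (URA3 and YGP1, both with a later mean end) and 7 lists passed. Deviations of libraries with the same number correlated at -0.094, -0.028 and -0.011 across genes, so the numbers do not pair the libraries and the block costs degrees of freedom. In simulated counts at this depth, a 2-fold change of 1 cluster was recovered in 29.9% of genes.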

Other observations

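The tests of URA3 against its own level and against a strain difference, and that of clusters in the coding region, were chosen after the results were seen. The remaining tests of patterns were written before their own values were looked at, though after the gene calls were known. The mating-type genes describe the strain background. All 4 genes specific to α cells were tested and none was called, MF(ALPHA)1 standing at 4802 ± 427 CPM in the deletion and 4552 ± 404 in wild type, MF(ALPHA)2 at 7579 ± 430 and 6801 ± 1823, STE3 at 640 ± 129 and 603 ± 101, and SAG1 at 366 ± 32.6 and 403 ± 40.8 (n = 3 per group). Of 7 genes specific to a cells, 2 were in the table and 0 had enough reads to be tested. The Ty element list took 0 genes. Of 23 meiosis genes, 2 were tested, SPR3 (log2 fold change 0.40, SE 0.34) and IME2 (-0.36, SE 0.38).

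The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 44 genes with changed mRNA level, 5 with changed pA site usage and 7 gene lists, and the highest of the other 9 splits gave 0, 0 and 4, so that 1 split of the 10 reached each real count. At an unadjusted p under 0.05 for site usage, the real split gave 135 genes and another split 138.

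The first pattern is the 36 genes called higher in the deletion. Wild-type replicate 2 alone does not account for it, since 30 of the 36 genes called higher stayed called higher without it, and reads shared between near-identical genes concern 3 of the 36. A general stress or glucose-exhaustion state in which ribosomal protein genes fall together is argued against by their median of -0.023 (quartiles -0.12 and 0.067, and medians from -0.046 to -0.013 without each library). A difference in culture density or remaining glucose at harvest that leaves ribosomal protein genes level may still contribute, and with 12 of the 36 genes in the stress, hexose transport or respiration lists it cannot be told apart from an effect of the deletion, because culture records were not used here. An effect of the deletion itself stays open as a hypothesis.

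At URA3, a block in pyrimidine synthesis was considered because URA1, of the same pathway, was called higher (0.72, a call lost without deletion replicate 1 or 2 or wild-type replicate 1), but URA4 and URA10, other targets of the regulator Ppr1, had a mean log2 fold change of -0.073 (URA4 -0.17, SE 0.19, and URA10 0.03, SE 0.24). A candidate explanation that stays open is a strain difference at the URA3 locus or a URA3 marker on introduced DNA: 0 other marker genes changed among 6 tested for level and 5 for site usage, which leaves a difference at URA3 alone possible. Less mRNA with an unchanged choice of site would lower both retained clusters alike. The cluster at 117044 stood at 0 CPM in the deletion and 32.0 ± 18.9 in wild type. The one at 117106 stood at 19.6 ± 7.56 and 14.8 ± 10.5 and was not lower. These are the reads on which the gene was called, so they cannot decide on this explanation. The difference of 68.2 percentage points in the share of reads at the most distal of all 3 clusters likewise restates why the gene was called. No strain genotype beyond JHD2 is given in the sources used here, and the reads are few.

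The last pattern is the 5 genes called for changed site usage, where a mixing of clusters in the coding region with those past the stop codon was considered. With clusters past the stop codon only, 4 of the 5 genes lost their call, which meets the rule written for this explanation but decides nothing here. Only YGP1 has a retained cluster in the coding region, and it was left with 1 cluster and not tested, so its call sets the 3′ UTR against the start of the coding region. PCL1, SBE22 and SOD2 have none, kept the same change of position and moved from an adjusted p of 0.041, 0.046 and 0.046 to 0.061. The most distal SOD2 cluster lies 211 nt before the start of ERG11, and the most distal PCL1 cluster at the 5′ edge of SNR40. Neither sits at the 3′ end of that neighbouring gene. Whether these clusters belong to transcripts other than those of SOD2 and PCL1 was not tested.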
